A study of Drosophila melanogaster with 58 samples.

How the data were processed

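Total RNA from heads of adult male flies was labelled from 250 ng with a 3′ IVT kit and measured on the Affymetrix Drosophila Genome 2.0 array, per the labels' protocols. The deposited series table holds log2 values made by the authors with RMA, per the submitters' processing notes, which also name limma; versions and settings are not given in the sources used here. RMA subtracts background, quantile normalizes and summarizes probes by median polish, so a change shared by most transcripts would be removed from these values and dim probe sets carry compressed differences. Array medians ran from 3.7 to 3.87 and values from 1.52 to 13.9. The table has 18952 probe sets on 58 arrays and 0 columns of other samples. The 183 control probe sets were left out, which left 18769. In the platform annotation 13647 probe sets have 1 gene symbol, 402 several and 4720 none; 13544 of those with 1 symbol were matched to RefSeq gene identifiers for current symbols. For gene lists, the probe set with the highest mean over all arrays stood for each of 11982 genes.

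Groups were taken from the labels. One limma fit (version 3.58.1, R 4.3.3) with a mean per group was made over all 58 arrays, with empirical Bayes moderation (43 residual and 3.88 prior degrees of freedom), and Benjamini-Hochberg adjustment was done within each comparison. A probe set was called at an adjusted p under 0.05, and rose, fell and changed refer to called ones. PTZ and the 7 other single compounds were compared with normal food, the 6 combinations with PTZ, and the 5 drugs given both ways were tested for a difference between their effects. Camera tested 36 lists with a preset correlation of 0.01 and at least 5 measured genes, adjusted within each comparison, and again with a correlation estimated per list. The lists were cytochrome P450s of the xenobiotic families, glutathione S-transferases, UDP-glycosyltransferases, heat shock and chaperone genes, antimicrobial peptides and Toll/Imd effectors, Turandot and JAK/STAT stress genes, oxidative stress genes, circadian clock genes, phototransduction and retina markers, voltage-gated and potassium channels, GABA and glutamate signalling genes, synaptic vesicle and active zone genes, monoamine signalling genes, cholinergic signalling genes, neuropeptide genes, activity-regulated genes, glia markers, pan-neuronal markers, fat body and adipose secreted genes, female yolk protein and egg genes, testis and accessory gland genes, gut digestive enzymes, muscle markers, odorant binding proteins and antennal markers, cuticle protein genes, glycolysis enzymes, fatty acid and triglyceride metabolism genes, fatty acid beta-oxidation and peroxisome genes, oxidative phosphorylation subunits, cytosolic ribosomal proteins, mitochondrial ribosomal proteins, proteasome subunits, insulin, FOXO and starvation genes, hexosamine, chitin and polyol metabolism genes, sugar transporters, and reported targets of the compounds or their fly relatives. Slopes and correlations across probe sets used disjoint sets of 2 of the shared reference arrays, averaged over 6 splits, and were simulated for unchanged groups 20 times. Figures were drawn with Python 3.11.15 and matplotlib 3.10.9.

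The design, the lists, the rule for named genes and the first group of alternatives in the next paragraph were set before the data were examined. The rule took genes with exactly 1 symbol: among called genes whose groups of arrays do not overlap, the 8 greatest rises and falls for PTZ, levetiracetam and their combination, 4 and 4 for the other comparisons, 2 and 2 for each difference of effects without the overlap condition, up to 4 called members of each called list, and any reported target. A part of the genes it allows is named. Where another probe set of a named gene disagreed, this is said.

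The first group of alternatives was a variance trend with a robust prior, a second quantile normalization, leaving out the 40% of probe sets with the lowest mean, fitting only the groups compared, the replicate number as a block, leaving out each array in turn, unsplit references, a correlation estimated per list and the mean of a gene's probe sets. Further alternatives were chosen after seeing the data. References were the mean of other groups of the kind (7 compounds without PTZ, or combinations) or, for slopes, the PTZ change of other backgrounds. The 5′ to 3′ control signal was a covariate or was removed by its slope within groups. The bioB level was a block, or only arrays of its lower level were used. PTZ was also tested over pairs of group means (6 pairs, 5 without normal food, or 5 without glucosamine). The 5′ to 3′ signal is the mean over eIF-4a and GAPDH of the 5′ minus the 3′ control probe set, and bioB levels were separated at a bioB minus bioC of -3.

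The code was tested on simulated data with 18769 probe sets, 50 of them changed at each size. For PTZ against normal food, 42% of changes of 0.25, 96% of 0.5 and 100% of 1 were recovered; for moxifloxacin, with 2 arrays, 30%, 84% and 100%; for the levetiracetam difference of effects, 20%, 72% and 100%. No 2 arrays held identical values. No scan date, detection call or background was used here.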

Results

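Transcript profiles were taken from the heads of Oregon R fruit flies, a common wild-type laboratory strain. Adult unmated males, 10 days old at collection and kept 30 to a vial, had eaten plain food or food with 1 or 2 compounds for 7 days at 25 degrees C. The 58 arrays fell into 15 groups of 4, except moxifloxacin with 2. The groups were normal food, pentylenetetrazole (PTZ), 7 compounds without PTZ (levetiracetam, glucosamine, mannitol, olmesartan, moxifloxacin, gemfibrozil and quinapril) and 6 combinations of PTZ with levetiracetam, glucosamine, mannitol, olmesartan, quinapril or oxaprozin. Doses are not given in the sources used here. The series title speaks of a screen for drugs that could be given a new use in neuropsychiatry. Changes are given on the log2 scale ± SE, levels as group means ± SD of the arrays, and adjusted p-values come from limma. The number of arrays limits the precision, and changes to or from levels near the lower end of the scale are of uncertain size, since probe sets were not tested against background.

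Arrays of one group lay close together. The median SD within a group was 0.0547 to 0.0932, against a median SD of 0.233 between the 15 group means, and each of the 58 arrays correlated best with an array of its own group. The labels do not say that the arrays of a group came from separate cultures, so the p-values measure only the spread between these arrays, which may be technical. Any pair of groups therefore differed in many probe sets: the 21 pairs among the 7 compounds without PTZ differed in 4198 to 9255 probe sets, and the 15 pairs among the 6 combinations in 3776 to 9541. A count of calls against one reference group is to be read beside those numbers.

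Several measures of tissue and array quality moved with the groups. Testis and accessory gland genes, which a head sample would hold at low levels, had a median level of 6.32 ± 0.051 in normal food, 5.04 ± 0.10 in moxifloxacin, 4.56 ± 0.23 in levetiracetam, 3.81 ± 0.10 in gemfibrozil and 3.32 ± 0.12 in PTZ. The difference between the 5′ and 3′ signals of the eIF-4a and GAPDH control probe sets, which falls as transcripts shorten, was -6.42 ± 0.22 in normal food, -5.67 ± 0.089 in PTZ, -4.14 ± 0.23 in PTZ with levetiracetam and -4.73 ± 0.17 in PTZ with oxaprozin. The bioB hybridization control, a bacterial transcript added to each array, lay at an upper level relative to bioC on 20 arrays and at a lower level on 38. The upper level held every array of mannitol, moxifloxacin, gemfibrozil, PTZ with glucosamine and PTZ with mannitol, and 1 array each of olmesartan and quinapril.

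**Figure D1:**
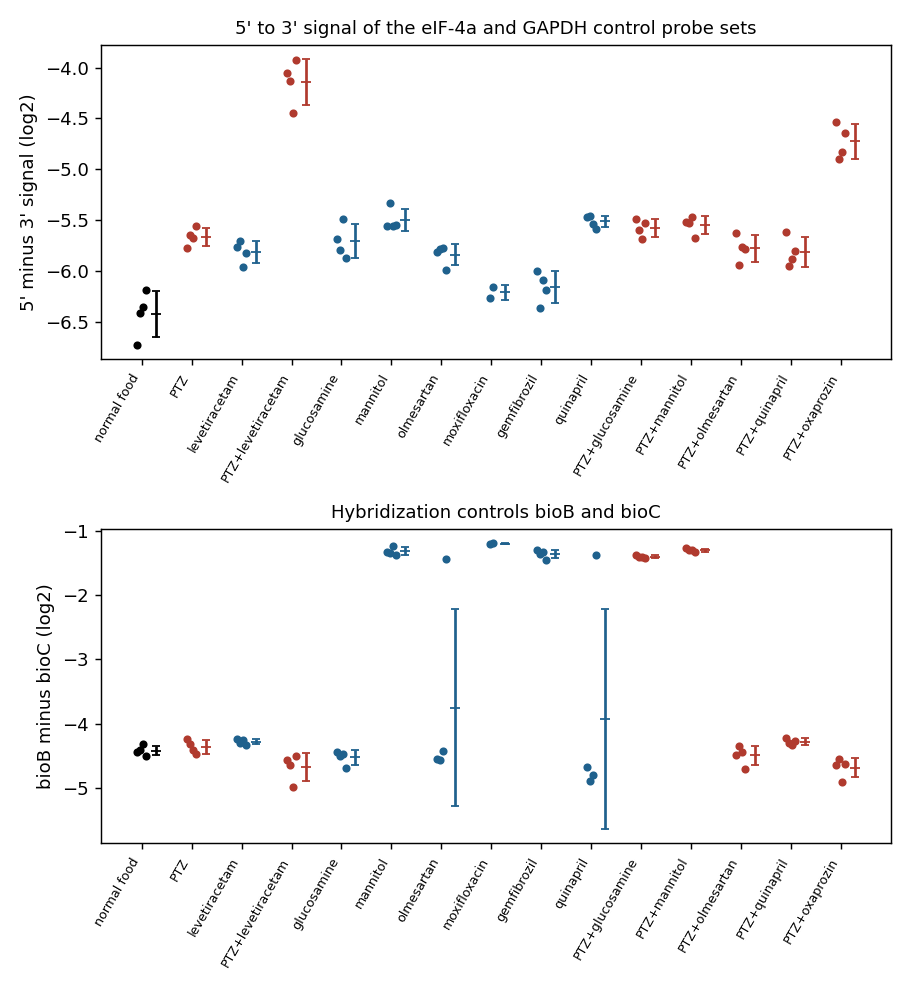
Signal of 2 kinds of control probe sets on each of the 58 arrays, by group, in log2 units: the 5′ minus 3′ signal of eIF-4a and GAPDH (upper) and bioB minus bioC (lower), with points for arrays and bars for the mean ± SD. PTZ with levetiracetam (-4.14 ± 0.23) and PTZ with oxaprozin (-4.73 ± 0.17) lie above the other groups in the upper panel, and 20 arrays lie at the upper level in the lower panel.

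PTZ, a convulsant that blocks GABA-A-type chloride channels and is used to model epilepsy, was set against normal food to ask what a week of feeding changed in the head. Gnmt, a glycine N-methyltransferase, rose 15.2-fold, from a level of 7.12 ± 0.15 to 11.04 ± 0.042 (SD, n = 4 each; log2 change 3.92 ± 0.060, adjusted p = 5.71e-44). Similar rises were measured for CG3999, the glycine decarboxylase of the glycine cleavage system (3.78 ± 0.071), Nmdmc, a methylenetetrahydrofolate dehydrogenase (3.23 ± 0.084), Ahcy, which hydrolyses S-adenosylhomocysteine (2.95 ± 0.087), and hll, an acyl-CoA synthetase (3.88 ± 0.077). Detoxification enzymes and antimicrobial peptides rose too, while genes of the male reproductive tract fell. EbpII and Ebp, proteins of the ejaculatory bulb, fell by 5.85 ± 0.11 and 6.38 ± 0.11, and Acp98AB, an accessory gland protein, by 5.25 ± 0.12.

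In total limma called 4493 probe sets higher and 4949 lower (849 by at least 2-fold) and 19 of the 36 gene lists (12 also with an estimated correlation). Among cytochrome P450s of the xenobiotic families, 49 of 65 rose, 6 fell and 10 were not called (57 called when adjusted over the list alone, median 0.46, camera adjusted p = 7.12e-11). Cyp6a8, Cyp6w1 and Cyp6a2, members linked to the handling of foreign compounds, rose by 2.87 ± 0.045, 2.48 ± 0.036 and 2.20 ± 0.052, whereas Cyp4g1, which makes cuticular hydrocarbons, fell by 1.86 ± 0.11. Of the glutathione S-transferases, 26 of 34 rose, 2 fell and 6 were not called (29 called when adjusted over the list alone, median 0.60, camera adjusted p = 2.65e-09), led by GstD2 (2.93 ± 0.062) and GstD1 (1.37 ± 0.048). Antimicrobial peptides and Toll/Imd effectors followed: 12 of 18 rose, 2 fell and 4 were not called (14 called when adjusted over the list alone, median 0.45, camera adjusted p = 0.000144). Def, DptB, Drs and Mtk, which encode secreted antimicrobial peptides, rose by 2.99 ± 0.051, 2.78 ± 0.061, 1.86 ± 0.048 and 1.27 ± 0.045. In the heat shock and chaperone list 9 of 12 rose, 1 fell and 2 were not called (11 called when adjusted over the list alone, median 0.45, camera adjusted p = 0.00279), with Hsp26 at 2.74 ± 0.074, Hsp68 at 1.39 ± 0.088 and Hsp27 at 1.16 ± 0.078.

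Genes of neurons went the other way after PTZ. Of the pan-neuronal markers, 1 of 13 rose, 12 fell and 0 were not called (13 called when adjusted over the list alone, median -0.53, camera adjusted p = 1.31e-05), among them fne, which encodes an ELAV-type RNA-binding protein (-0.85 ± 0.028), and Appl, the fly amyloid precursor protein-like gene (-0.81 ± 0.031). Of the synaptic vesicle and active zone genes, 3 of 30 rose, 20 fell and 7 were not called (24 called when adjusted over the list alone, median -0.34, camera adjusted p = 0.000107), including nSyb, the neuronal synaptobrevin (-0.64 ± 0.056). For cholinergic signalling genes, 3 of 14 rose, 10 fell and 1 was not called (14 called when adjusted over the list alone, median -0.29, camera adjusted p = 0.000551), with the receptor subunits nAChRalpha4 at -1.39 ± 0.060 and nAChRalpha7 at -1.34 ± 0.051. Rdl, a GABA-A-type receptor subunit, was at 0.032 ± 0.048 and was not called (adjusted p = 0.615). Mitochondrial ribosomal proteins rose: 67 of 71 rose, 0 fell and 4 were not called (68 called when adjusted over the list alone, median 0.48, camera adjusted p = 1.46e-13). Of the proteasome subunits, 26 of 40 rose, 5 fell and 9 were not called (32 called when adjusted over the list alone, median 0.79, camera adjusted p = 8.85e-09), with Rpn7 at 1.55 ± 0.071 and Rpn1 at 1.42 ± 0.093. Testis and accessory gland genes fell: 1 of 33 rose, 31 fell and 1 was not called (32 called when adjusted over the list alone, median -3.05, camera adjusted p = 4.71e-21). Of the gut digestive enzymes, 6 of 39 rose, 20 fell and 13 were not called (26 called when adjusted over the list alone, median -0.31, camera adjusted p = 0.00162), with the maltase Mal-A1 at -2.92 ± 0.082, the trypsin betaTry at -2.87 ± 0.13 and the serine protease Jon65Aiii at -2.85 ± 0.13.

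Normal food stood above every other group in testis and accessory gland genes, so PTZ was also set against the mean of the 7 compounds without PTZ. There Gnmt (3.03), hll (3.33), GstD2 (2.89) and Cyp6a8 (2.84) kept their direction, Def, DptB, Rpn7, Rpn1, nSyb, Ebp, Acp98AB, Mal-A1 and betaTry were at 1.12, 1.04, 0.63, 0.69, -0.27, -0.90, -0.41, -0.40 and -0.34, and EbpII turned to 0.12 (adjusted p = 0.284) and Cyp4g1 to 1.46 (adjusted p = 8.88e-20). Jon65Aiii, nAChRalpha4 and the antimicrobial and gut lists were no longer called (adjusted p = 0.0875, 0.078, 0.183 and 0.914), while the testis list stayed lower (median -0.24, adjusted p = 0.000334).

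The PTZ change could also be measured across the 6 backgrounds that were fed both with and without it (no drug, levetiracetam, glucosamine, mannitol, olmesartan and quinapril), with each pair of group means as one unit. On that footing 222 probe sets were called higher and 332 lower. Gnmt rose by 3.14, hll by 3.35, GstD2 by 2.57 and Cyp6a8 by 2.54. Lists called higher were P450s (median 0.18, camera adjusted p = 1.05e-05), glutathione S-transferases (0.20, 1.26e-05), mitochondrial ribosomal proteins (0.26, 1.04e-11) and proteasome subunits (0.32, 0.000485). Lists of pan-neuronal markers (median -0.35, camera adjusted p = 3.29e-05), voltage-gated and potassium channels (median -0.15, camera adjusted p = 0.000485), cholinergic genes (median -0.13, camera adjusted p = 0.000875) and synaptic genes (median -0.16, camera adjusted p = 0.00281) were called lower. So was the testis and accessory gland list (median -0.70, camera adjusted p = 0.000285), also over the 5 pairs without normal food (-0.24, 0.0354) and the 5 of one bioB level (-0.91, 1.18e-05). Antimicrobial genes were not called over the 6 pairs (median -0.12, camera adjusted p = 0.42) and were called lower over the 5 pairs without normal food (median -0.16, camera adjusted p = 0.022). Heat shock genes (camera adjusted p = 0.297 and 0.452) and gut enzymes (0.898 and 0.144) were called in neither. Over the 6 pairs 25 of the 42 named genes, among them GstD1, Drs, Hsp26, nAChRalpha4 and nSyb, were no longer called and 4 turned. Over the 5 pairs DptB and Mtk turned to -1.10 and -1.13.

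**Figure D2:**
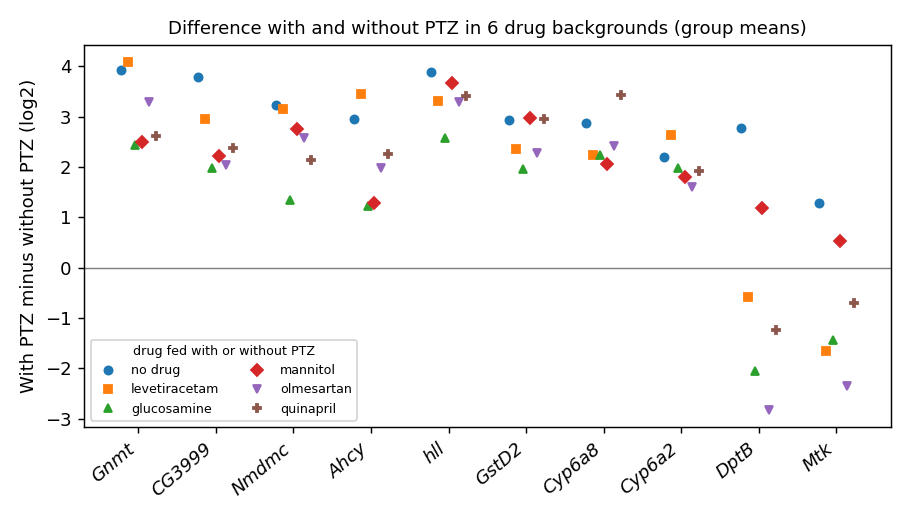
Difference between group means with and without PTZ (log2) for 10 genes in 6 drug backgrounds, one symbol per background. Gnmt, CG3999, Nmdmc, Ahcy, hll, GstD2, Cyp6a8 and Cyp6a2 lie above 0 in all 6 backgrounds, whereas DptB and Mtk lie on both sides of 0.

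Levetiracetam, an antiepileptic that binds the synaptic vesicle protein SV2A, was fed alone to see its own effect. TotC, a secreted stress peptide of the Turandot family, rose 3.96-fold (1.98 ± 0.076, level 8.19 ± 0.025 against 6.21 ± 0.17, SD, n = 4 each, adjusted p = 1.07e-26). The haemocyte receptors Sr-CI and NimC1 rose by 1.44 ± 0.088 and 1.33 ± 0.090. EbpII and Ebp fell by 6.05 ± 0.11 and 5.90 ± 0.11, and Anp, an antibacterial peptide gene of the ejaculatory duct, fell by 4.44 ± 0.10. In all, limma called 3939 probe sets higher and 3246 lower (245 by at least 2-fold) and 16 of the 36 gene lists (6 also with an estimated correlation). Circadian clock genes were one called list: 7 of 12 rose, 0 fell and 5 were not called (8 called when adjusted over the list alone, median 0.17, camera adjusted p = 0.0309, and adjusted p = 0.0543 with an estimated correlation), with per, tim and Clk at 0.39 ± 0.070, 0.30 ± 0.033 and 0.24 ± 0.053, though another probe set of tim was not called; with the 5′ to 3′ signal as a covariate per and Clk were at 0.19 and 0.12 and were not called. Of the muscle markers, 14 of 22 rose, 3 fell and 5 were not called (17 called when adjusted over the list alone, median 0.15, camera adjusted p = 0.0133), including the actin gene Act79B (0.74 ± 0.048). Of the fatty acid beta-oxidation and peroxisome genes, 18 of 26 rose, 2 fell and 6 were not called (20 called when adjusted over the list alone, median 0.34, camera adjusted p = 5.06e-06, and adjusted p = 0.133 with an estimated correlation), with the thiolase yip2 at 0.71 ± 0.041. Insulin, FOXO and starvation genes were called in this comparison alone among the 14. In that list 11 of 26 rose, 4 fell and 11 were not called (17 called when adjusted over the list alone, median 0.12, camera adjusted p = 0.0309, and adjusted p = 0.0514 with an estimated correlation). Rdl rose by 0.32 ± 0.048. Of the P450s, 42 of 65 rose, 5 fell and 18 were not called (47 called when adjusted over the list alone, median 0.26, camera adjusted p = 2.7e-07). Among testis and accessory gland genes, 1 of 33 rose, 28 fell and 4 were not called (29 called when adjusted over the list alone, median -0.85, camera adjusted p = 7.26e-18).

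The reference mattered for levetiracetam. Against the mean of the other 6 compounds without PTZ, TotC stayed higher (0.67), Sr-CI, Rdl, Ebp and Anp were at 0.53, 0.15, -0.49 and -0.63, and EbpII, NimC1 and the insulin list were no longer called (adjusted p = 0.418, 0.0524 and 0.73). DptB, Def, yip2, Lsp2 and fit, called higher against normal food at 1.25 ± 0.061, 1.20 ± 0.051, 0.71 ± 0.041, 1.21 ± 0.040 and 1.06 ± 0.042, turned to -0.57, -0.79, -0.43, -0.14 and -0.47. CG7953 and Jon65Aiii, called lower at -3.97 ± 0.10 and -2.27 ± 0.13, turned to 0.28 and 0.44. The P450, beta-oxidation and testis lists turned to medians of -0.082, -0.080 and 1.22 (adjusted p = 0.00688, 0.0139 and 3.7e-13).

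With glucosamine, an amino sugar, the antimicrobial peptide genes DptB and Def rose by 1.91 ± 0.061 and 1.62 ± 0.051 (DptB level 8.07 ± 0.063 against 6.16 ± 0.095, SD, n = 4 each). Lsp2, a storage protein of the fat body, rose by 1.54 ± 0.040, and Pepck1, which makes phosphoenolpyruvate for gluconeogenesis, by 1.54 ± 0.055. The accessory gland genes Acp98AB and Mst57Da fell by 7.30 ± 0.12 and 6.41 ± 0.10 (adjusted p at most 1.29e-28 for these genes). Gfat1, which starts hexosamine synthesis, rose by 0.38 ± 0.035 with its brightest probe set, while its other probe set had the opposite sign and was not called. Altogether limma called 4213 probe sets higher and 3556 lower (364 by at least 2-fold) and 18 of the 36 gene lists (8 also with an estimated correlation). Of the antimicrobial peptides and Toll/Imd effectors, 11 of 18 rose, 2 fell and 5 were not called (13 called when adjusted over the list alone, median 0.42, camera adjusted p = 5.4e-05). Odorant binding proteins and antennal markers were called higher. In that list 31 of 55 rose, 4 fell and 20 were not called (39 called when adjusted over the list alone, median 0.29, camera adjusted p = 2.57e-05). Of the fat body and adipose secreted genes, 10 of 17 rose, 1 fell and 6 were not called (11 called when adjusted over the list alone, median 0.14, camera adjusted p = 0.000448). Activity-regulated genes were called lower: 2 of 14 rose, 8 fell and 4 were not called (10 called when adjusted over the list alone, median -0.20, camera adjusted p = 0.0225). Testis and accessory gland genes stood at 2.60 ± 0.067 as a list median; 0 of 33 rose, 30 fell and 3 were not called (30 called when adjusted over the list alone, median -3.27, camera adjusted p = 3.58e-39). Hexosamine, chitin and polyol metabolism genes were not called: 7 of 23 were called higher, 2 lower and 14 not called, with 9 called when adjusted over the list alone (median 0.070, camera adjusted p = 0.286). Relative to the other compounds without PTZ, DptB, Lsp2, Acp98AB and Mst57Da were at 0.20, 0.24, -2.87 and -2.45, Def, Gfat1 and the antennal list turned to -0.30, -0.29 and a median of -0.097 (adjusted p = 0.0119 for the list), and Pepck1 and the antimicrobial, fat body and activity-regulated lists were no longer called (adjusted p = 0.485, 0.105, 0.0562 and 0.131). With the 5′ to 3′ signal difference as a covariate, 4997 probe sets were called in place of 7769.

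With mannitol, a sugar alcohol, CAH5, a carbonic anhydrase, rose by 2.79 ± 0.060 (level 9.36 ± 0.047 against 6.57 ± 0.085, SD, n = 4 each, adjusted p = 3.72e-38) and Pepck1 by 2.27 ± 0.055. The glutathione S-transferase genes GstE1 and GstE3 rose by 1.55 ± 0.051 and 1.39 ± 0.038, the proteasome subunit gene Prosbeta2 by 1.74 ± 0.051 and the small heat shock gene Hsp26 by 1.67 ± 0.074. Sodh1, a sorbitol dehydrogenase of polyol metabolism, rose by 1.11 ± 0.051. CadN, a neuronal cadherin, fell by 0.96 ± 0.071. The comparison had many calls, as limma called 4291 probe sets higher and 4763 lower (925 by at least 2-fold) and 23 of the 36 gene lists (14 also with an estimated correlation). Of the glutathione S-transferases, 27 of 34 rose, 1 fell and 6 were not called (28 called when adjusted over the list alone, median 0.60, camera adjusted p = 1.16e-08). UDP-glycosyltransferases were also called higher. In that list 17 of 35 rose, 4 fell and 14 were not called (21 called when adjusted over the list alone, median 0.14, camera adjusted p = 0.0299, and adjusted p = 0.076 with an estimated correlation). Of the oxidative stress genes, 11 of 17 rose, 3 fell and 3 were not called (16 called when adjusted over the list alone, median 0.49, camera adjusted p = 0.000396, and adjusted p = 0.0651 with an estimated correlation). Muscle markers fell: 3 of 22 rose, 19 fell and 0 were not called (22 called when adjusted over the list alone, median -0.45, camera adjusted p = 5.25e-05). Of the glia markers, 12 of 20 rose, 6 fell and 2 were not called (18 called when adjusted over the list alone, median 0.29, camera adjusted p = 0.0233). Glycolysis enzymes were called higher. In that list 9 of 14 rose, 3 fell and 2 were not called (14 called when adjusted over the list alone, median 0.25, camera adjusted p = 0.0176, and adjusted p = 0.076 with an estimated correlation). Acp98AB, EbpII and Mst57Da fell by 7.30 ± 0.12, 7.90 ± 0.11 and 6.41 ± 0.10. In the testis and accessory gland list 0 of 33 rose, 30 fell and 3 were not called (30 called when adjusted over the list alone, median -3.28, camera adjusted p = 1.53e-20). With the other compounds without PTZ as reference, CAH5, Pepck1, Prosbeta2, Sodh1, Acp98AB, EbpII and Mst57Da were at 1.37, 0.89, 0.78, 0.46, -2.86, -2.25 and -2.45, and the UDP-glycosyltransferase list was no longer called (adjusted p = 0.0827). All 4 mannitol arrays lay at the upper bioB level and the normal food arrays at the lower.

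With olmesartan, an angiotensin receptor blocker, Def and DptB rose by 2.98 ± 0.051 and 2.87 ± 0.061 (levels 9.55 ± 0.0070 against 6.56 ± 0.12 and 9.03 ± 0.092 against 6.16 ± 0.095, SD, n = 4 each, adjusted p at most 1.89e-38). Obp19a, an odorant binding protein, rose by 1.92 ± 0.15, and CG13428 by 2.77 ± 0.055. The neuronal genes elav, which encodes an RNA-binding protein, and nSyb fell by 0.84 ± 0.050 and 0.75 ± 0.056. Ance, a relative of angiotensin-converting enzyme, rose by 1.03 ± 0.066. In the full set limma called 4829 probe sets higher and 4571 lower (836 by at least 2-fold) and 21 of the 36 gene lists (13 also with an estimated correlation). Odorant binding proteins and antennal markers rose: 37 of 55 rose, 4 fell and 14 were not called (41 called when adjusted over the list alone, median 0.68, camera adjusted p = 3.41e-08). Of the oxidative phosphorylation subunits, 52 of 76 rose, 12 fell and 12 were not called (64 called when adjusted over the list alone, median 0.47, camera adjusted p = 2.13e-08, and adjusted p = 0.0516 with an estimated correlation). Monoamine signalling genes were called lower. In that list 5 of 26 rose, 14 fell and 7 were not called (21 called when adjusted over the list alone, median -0.21, camera adjusted p = 0.0262, and adjusted p = 0.0516 with an estimated correlation). Of the activity-regulated genes, 1 of 14 rose, 11 fell and 2 were not called (12 called when adjusted over the list alone, median -0.23, camera adjusted p = 0.00167). In the list of reported targets of the compounds or their fly relatives, 12 of 20 rose, 1 fell and 7 were not called (15 called when adjusted over the list alone, median 0.25, camera adjusted p = 0.00302, and adjusted p = 0.0606 with an estimated correlation). Testis and accessory gland genes were lower, with Acp98AB at -6.84 ± 0.12; 1 of 33 rose, 30 fell and 2 were not called (31 called when adjusted over the list alone, median -3.13, camera adjusted p = 3.27e-21). Set against the other compounds without PTZ, Def, DptB, Ance, elav and Acp98AB were at 1.29, 1.33, 0.39, -0.33 and -2.33, and the monoamine list was no longer called (adjusted p = 0.178).

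Moxifloxacin, a fluoroquinolone antibiotic, was measured on 2 arrays. Dup99B, a peptide of the ejaculatory duct, rose from 2.43 ± 0.20 (SD, n = 4) to 7.13 ± 0.13 (SD, n = 2), a change of 4.70 ± 0.13 (limma adjusted p = 1.28e-32), with the normal food level near the lower end of the scale. Muc68D, a mucin-type gene, and CG14645 rose by 3.09 ± 0.14 and 2.49 ± 0.16, and the neuropeptide gene NPF by 1.68 ± 0.073. Hsp68 fell by 0.59 ± 0.11. The potassium channel beta subunit Hk fell by 1.07 ± 0.067, although its other 2 probe sets were not called. The DNA topoisomerase gene Top3alpha fell by 0.68 ± 0.13. With 2 arrays in the group, limma called 3311 probe sets higher and 3727 lower (418 by at least 2-fold) and 16 of the 36 gene lists (12 also with an estimated correlation). Among antimicrobial peptides and Toll/Imd effectors, 12 of 18 rose, 2 fell and 4 were not called (16 called when adjusted over the list alone, median 0.57, camera adjusted p = 1.22e-06). Heat shock and chaperone genes were lower: 3 of 12 rose, 8 fell and 1 was not called (11 called when adjusted over the list alone, median -0.35, camera adjusted p = 0.0227). Of the voltage-gated and potassium channels, 4 of 31 rose, 14 fell and 13 were not called (18 called when adjusted over the list alone, median -0.19, camera adjusted p = 0.00603). Neuropeptide genes were called higher. In that list 14 of 36 rose, 7 fell and 15 were not called (23 called when adjusted over the list alone, median 0.15, camera adjusted p = 0.0227). The testis and accessory gland list was lower: 3 of 33 rose, 25 fell and 5 were not called (31 called when adjusted over the list alone, median -0.79, camera adjusted p = 2.14e-08). Against the mean of the other compounds without PTZ, NPF was at 0.31, that list turned to a median of 1.60 (adjusted p = 2.98e-22), and Ebp, CG18628, CG7953 and CG8997, called lower at -3.30 ± 0.14, -3.73 ± 0.15, -3.36 ± 0.12 and -3.23 ± 0.11, turned to 2.54, 1.70, 0.99 and 0.60. The antimicrobial and neuropeptide lists were no longer called there (adjusted p = 0.156 and 0.372). Both moxifloxacin arrays lay at the upper bioB level.

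With gemfibrozil, a lipid-lowering fibrate, the heat shock genes Hsp26, Hsp68 and Hsp27 rose by 2.44 ± 0.074, 2.36 ± 0.088 and 1.87 ± 0.078 (Hsp68 level 7.58 ± 0.054 against 5.22 ± 0.12, SD, n = 4 each, adjusted p = 4.65e-28). Genes of muscle rose with them: Scp1, a sarcoplasmic calcium-binding protein, by 2.13 ± 0.040, Act79B by 1.46 ± 0.048 and TpnC41C, a troponin C, by 1.32 ± 0.036. The RNA-binding protein gene elav fell by 1.45 ± 0.050. By count, limma called 4742 probe sets higher and 3899 lower (681 by at least 2-fold) and 18 of the 36 gene lists (9 also with an estimated correlation). Of the muscle markers, 15 of 22 rose, 3 fell and 4 were not called (19 called when adjusted over the list alone, median 0.36, camera adjusted p = 0.000182). Heat shock and chaperone genes rose: 7 of 12 rose, 2 fell and 3 were not called (9 called when adjusted over the list alone, median 0.34, camera adjusted p = 0.0153). Of the fatty acid beta-oxidation and peroxisome genes, 21 of 26 rose, 1 fell and 4 were not called (22 called when adjusted over the list alone, median 0.30, camera adjusted p = 0.000153, and adjusted p = 0.171 with an estimated correlation). Cytosolic ribosomal proteins were called higher. In that list 27 of 42 rose, 3 fell and 12 were not called (31 called when adjusted over the list alone, median 0.22, camera adjusted p = 9.27e-07, and adjusted p = 0.0644 with an estimated correlation). Of the testis and accessory gland genes, 1 of 33 rose, 30 fell and 2 were not called (31 called when adjusted over the list alone, median -2.65, camera adjusted p = 3.85e-23), including the testis gene ocn at -4.27 ± 0.088. Relative to the other compounds without PTZ, ocn was at -0.38, the beta-oxidation and testis lists turned to medians of -0.058 and 0.13 (adjusted p = 0.0305 and 0.0557), and CG31226 and CG18628, called lower at -4.68 ± 0.098 and -4.30 ± 0.12, turned to 0.13 and 1.03. All 4 gemfibrozil arrays lay at the upper bioB level.

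With quinapril, an inhibitor of angiotensin-converting enzyme, the Turandot gene TotC rose 6.98-fold (2.80 ± 0.076, level 9.01 ± 0.058 against 6.21 ± 0.17, SD, n = 4 each, adjusted p = 1.18e-33). The troponin T gene up rose by 1.99 ± 0.069, inaD, a scaffold protein of photoreceptors, by 1.49 ± 0.047, and the neuropeptide gene Crz by 1.32 ± 0.050. Ance and Acer, the fly relatives of the enzyme that quinapril inhibits, rose by 0.78 ± 0.066 and 0.86 ± 0.039. EbpII and Acp98AB fell by 7.40 ± 0.11 and 7.01 ± 0.12. In this comparison limma called 4706 probe sets higher and 4501 lower (744 by at least 2-fold) and 17 of the 36 gene lists (5 also with an estimated correlation). Phototransduction and retina markers were called higher. In that list 14 of 24 rose, 8 fell and 2 were not called (23 called when adjusted over the list alone, median 0.18, camera adjusted p = 0.0396, and adjusted p = 0.227 with an estimated correlation). The activity-regulated genes were called lower: 1 of 14 rose, 9 fell and 4 were not called (10 called when adjusted over the list alone, median -0.27, camera adjusted p = 0.00741). Testis and accessory gland genes had a list median of 2.73 ± 0.058, and 0 of 33 rose, 30 fell and 3 were not called (30 called when adjusted over the list alone, median -3.37, camera adjusted p = 3.29e-22). With the other compounds without PTZ as reference, Acer, Crz, EbpII and Acp98AB were at 0.17, 0.60, -1.66 and -2.52, and Ance (0.10, adjusted p = 0.109) and the activity-regulated list (adjusted p = 0.144) were no longer called.

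**Figure D3:**
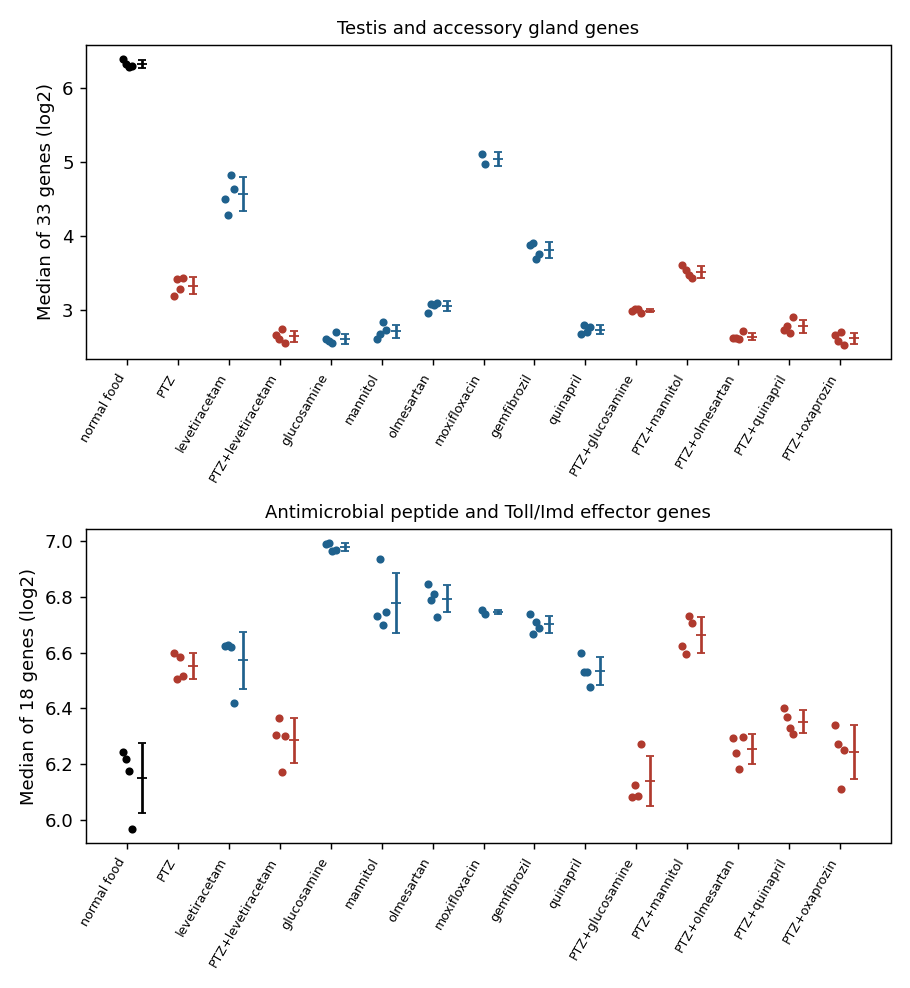
Median level (log2) of 33 testis and accessory gland genes (upper) and of 18 antimicrobial peptide and Toll/Imd effector genes (lower) on each array, by group, with points for arrays and bars for the mean ± SD; normal food is black, groups with PTZ red and compounds without PTZ blue. Normal food lies at 6.32 ± 0.051 in the upper panel, above every other group, and the lower panel places PTZ at 6.55 ± 0.047 and PTZ with glucosamine at 6.14 ± 0.089.

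Some lists were not called in any of the 14 comparisons against normal food or PTZ. GABA and glutamate signalling genes came nearest in PTZ with mannitol (median -0.048, adjusted p = 0.0607). Turandot and JAK/STAT stress genes did in moxifloxacin (0.23, 0.0757), and hexosamine, chitin and polyol metabolism genes in olmesartan (0.17, 0.231). Sugar transporters did in PTZ with oxaprozin (-0.11, 0.317). Cytosolic ribosomal proteins were called higher in 11 and oxidative phosphorylation subunits in 10 of the 14, and none of these calls held with an estimated correlation. Activity-regulated genes were called lower in 9 and testis and accessory gland genes in 13, and each held. With the other groups as reference several of both ended or turned. The comparisons share reference arrays, so these tallies are not independent.

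PTZ with levetiracetam was set against PTZ alone to see what the antiepileptic altered in flies fed the convulsant. TotC rose 6.93-fold (2.79 ± 0.076, level 8.70 ± 0.075 against 5.91 ± 0.13, SD, n = 4 each, adjusted p = 1.28e-32). The antimicrobial peptide genes Mtk, DptB and Drs fell by 2.33 ± 0.045, 2.11 ± 0.061 and 1.98 ± 0.048. The troponin T gene up rose (1.78 ± 0.069), as did ATPsynD, a subunit of ATP synthase (1.70 ± 0.061), and SdhB, a subunit of succinate dehydrogenase (1.45 ± 0.062). The sodium channel gene para rose by 1.02 ± 0.10, nSyb by 1.19 ± 0.056 and Rdl by 0.67 ± 0.048.

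Here limma called 3459 probe sets higher and 3759 lower (228 by at least 2-fold) and 12 of the 36 gene lists (3 also with an estimated correlation). Of the antimicrobial peptides and Toll/Imd effectors, 2 of 18 rose, 13 fell and 3 were not called (16 called when adjusted over the list alone, median -0.42, camera adjusted p = 7.99e-06). The pan-neuronal markers rose: 9 of 13 rose, 3 fell and 1 was not called (12 called when adjusted over the list alone, median 0.22, camera adjusted p = 0.0085). Of the synaptic vesicle and active zone genes, 3 of 30 rose, 16 fell and 11 were not called (19 called when adjusted over the list alone, median -0.21, camera adjusted p = 0.0392, and adjusted p = 0.272 with an estimated correlation). In the list of voltage-gated and potassium channels, 16 of 31 rose, 7 fell and 8 were not called (23 called when adjusted over the list alone, median 0.21, camera adjusted p = 0.0392, and adjusted p = 0.128 with an estimated correlation). Of the oxidative stress genes, 10 of 17 rose, 1 fell and 6 were not called (12 called when adjusted over the list alone, median 0.24, camera adjusted p = 0.000316, and adjusted p = 0.128 with an estimated correlation), with MsrA, a methionine sulfoxide reductase, at 1.03 ± 0.050 and Trxr1, a thioredoxin reductase, at 0.74 ± 0.060. Other probe sets of Msp300, a nesprin (1.81 ± 0.051), and of Rbp6, an RNA-binding protein (1.78 ± 0.079), disagreed: 1 of Msp300 was called lower, and 2 of Msp300 and 5 of Rbp6 were not called. The 5′ minus 3′ control signal was -4.14 ± 0.23 against -5.67 ± 0.089 in PTZ, and with it as a covariate 3419 probe sets were called in place of 7218, and para (0.51) and Trxr1 (0.24) were not called. Set against the other combinations, Mtk and Drs were at -0.60 and -0.16, DptB was at 0.055 and the synaptic list was no longer called (adjusted p = 0.358 and 0.242).

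PTZ with glucosamine had lower antimicrobial and heat shock genes than PTZ alone. DptB, Drs and Mtk fell by 2.93 ± 0.061, 2.28 ± 0.048 and 2.21 ± 0.045 (DptB level 6.01 ± 0.10 against 8.94 ± 0.035, SD, n = 4 each, adjusted p = 1.13e-37), and Hsp26 and Hsp68 by 1.92 ± 0.074 and 1.44 ± 0.088. Genes of neurons rose, among them nSyb (0.77 ± 0.056) and fne (0.79 ± 0.028). Cyp4g1, which makes cuticular hydrocarbons, rose by 1.46 ± 0.11, Obp99b, an odorant binding protein, by 1.86 ± 0.040 and Gfat1 by 0.21 ± 0.035. For this pair of groups limma called 2198 probe sets higher and 2334 lower (80 by at least 2-fold) and 19 of the 36 gene lists (12 also with an estimated correlation). Among antimicrobial peptides and Toll/Imd effectors, 1 of 18 rose, 13 fell and 4 were not called (14 called when adjusted over the list alone, median -0.29, camera adjusted p = 5.82e-09). Pan-neuronal markers were higher: 9 of 13 rose, 0 fell and 4 were not called (9 called when adjusted over the list alone, median 0.31, camera adjusted p = 1.43e-10). In the phototransduction and retina list, 15 of 24 rose, 0 fell and 9 were not called (18 called when adjusted over the list alone, median 0.16, camera adjusted p = 1.66e-09). Of the neuropeptide genes, 18 of 36 rose, 0 fell and 18 were not called (18 called when adjusted over the list alone, median 0.16, camera adjusted p = 1.54e-08). P450s were called lower. In that list 3 of 65 rose, 28 fell and 34 were not called (34 called when adjusted over the list alone, median -0.13, camera adjusted p = 0.000181). Of the fatty acid and triglyceride metabolism genes, 4 of 31 rose, 15 fell and 12 were not called (19 called when adjusted over the list alone, median -0.12, camera adjusted p = 0.0118). Female yolk protein and egg genes, measured as a check in male heads, were called higher: 5 of 15 rose, 0 fell and 10 were not called (5 called when adjusted over the list alone, median 0.20, camera adjusted p = 0.0089). Cuticle protein genes were also called higher. In that list 12 of 80 rose, 3 fell and 65 were not called (15 called when adjusted over the list alone, median 0.037, camera adjusted p = 0.0487, and adjusted p = 0.0537 with an estimated correlation). Against the mean of the other combinations, DptB, Drs, Mtk, Hsp26, Hsp68 and Gfat1 were at -0.93, -0.52, -0.46, -0.64, -0.36 and 0.089, and the antimicrobial, fatty acid, yolk and cuticle lists were no longer called (adjusted p = 0.0667, 0.236, 0.393 and 0.986). The 4 arrays lay at the upper bioB level, those of PTZ at the lower. A bioB block rested on 1 array each of olmesartan and quinapril, so the drop to 2146 calls may be imprecision.

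PTZ with mannitol had lower neuronal genes than PTZ alone. The RNA-binding protein gene elav fell by 1.12 ± 0.050 (adjusted p = 2.49e-24), and Hk by 1.28 ± 0.054, although 2 other probe sets of Hk were not called. Cyp4g1 fell by 2.38 ± 0.11, Ppn, which encodes the matrix protein papilin, by 1.92 ± 0.049 and the chaperone gene DnaJ-1 by 0.90 ± 0.032. The neuropeptide gene NPF rose by 1.24 ± 0.059 and Acp98AB by 1.45 ± 0.12. Numerically, limma called 2766 probe sets higher and 3521 lower (136 by at least 2-fold) and 13 of the 36 gene lists (7 also with an estimated correlation). Of the voltage-gated and potassium channels, 0 of 31 rose, 21 fell and 10 were not called (22 called when adjusted over the list alone, median -0.28, camera adjusted p = 1.63e-06). Monoamine signalling genes fell: 2 of 26 rose, 15 fell and 9 were not called (17 called when adjusted over the list alone, median -0.32, camera adjusted p = 0.000107). Of the glia markers, 2 of 20 rose, 13 fell and 5 were not called (15 called when adjusted over the list alone, median -0.24, camera adjusted p = 0.000491). Of the pan-neuronal markers 2 of 13 rose, 8 fell and 3 were not called (10 called when adjusted over the list alone, median -0.43, camera adjusted p = 0.00204). Heat shock and chaperone genes were lower: 1 of 12 rose, 10 fell and 1 was not called (11 called when adjusted over the list alone, median -0.39, camera adjusted p = 0.000107). The sorbitol dehydrogenase gene Sodh2 fell by 0.19 ± 0.059 and was at 0.052 against the mean of the other combinations, where Cyp4g1 was at -0.75 and the heat shock list was not called either (adjusted p = 0.387 and 0.115). All 4 arrays lay at the upper bioB level, and that block, as limited, gave 3948 calls.

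In PTZ with olmesartan, antimicrobial and muscle genes were lower than in PTZ alone. Os-C, Obp83b, a10 and a5, genes expressed in the antenna, rose by 3.13 ± 0.10, 2.60 ± 0.095, 1.98 ± 0.11 and 1.74 ± 0.12 (Os-C level 5.81 ± 0.088 against 2.68 ± 0.13, SD, n = 4 each, adjusted p = 3.7e-29). DptB, Mtk and Drs fell by 2.73 ± 0.061, 2.35 ± 0.045 and 1.99 ± 0.048, the muscle genes Scp1 and Act79B by 2.54 ± 0.040 and 1.11 ± 0.048, and Hsp26 by 1.97 ± 0.074. Ance fell by 0.36 ± 0.066. In this contrast limma called 2909 probe sets higher and 2797 lower (137 by at least 2-fold) and 9 of the 36 gene lists (7 also with an estimated correlation). Of the muscle markers, 1 of 22 rose, 14 fell and 7 were not called (17 called when adjusted over the list alone, median -0.20, camera adjusted p = 1.33e-07). Activity-regulated genes were lower: 0 of 14 rose, 10 fell and 4 were not called (10 called when adjusted over the list alone, median -0.22, camera adjusted p = 0.000206). Of the antimicrobial peptides and Toll/Imd effectors, 1 of 18 rose, 8 fell and 9 were not called (11 called when adjusted over the list alone, median -0.11, camera adjusted p = 0.000206). The antennal list as a whole was not called, as 15 of 55 were called higher, 14 lower and 26 not called, with 29 called when adjusted over the list alone (median 0.039, camera adjusted p = 0.104). Relative to the other combinations, DptB, Mtk, Drs and Hsp26 were at -0.69, -0.63, -0.17 and -0.71, and the antimicrobial list turned to a median of 0.18 (adjusted p = 0.593) and the activity-regulated list to -0.020 (adjusted p = 0.964).

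PTZ with quinapril had lower antimicrobial and heat shock genes than PTZ alone. Cyp4g1 fell by 4.30 ± 0.11 (level 3.88 ± 0.31 against 8.18 ± 0.046, SD, n = 4 each, adjusted p = 3.33e-33), and DptB and Drs by 2.42 ± 0.061 and 2.36 ± 0.048. Hsp26 and Hsp68 fell by 1.95 ± 0.074 and 1.63 ± 0.088, Lsd-1, a perilipin of lipid droplets, by 1.63 ± 0.046, and sr, an activity-regulated transcription factor, by 0.66 ± 0.083. Ance and Acer fell by 0.25 ± 0.066 and 0.32 ± 0.039, against a rise of both with quinapril alone. The gene whe rose by 1.35 ± 0.066. Across the arrays limma called 1844 probe sets higher and 2182 lower (49 by at least 2-fold) and 18 of the 36 gene lists (12 also with an estimated correlation). Among antimicrobial peptides and Toll/Imd effectors, 0 of 18 rose, 10 fell and 8 were not called (12 called when adjusted over the list alone, median -0.27, camera adjusted p = 2.94e-16). Activity-regulated genes were lower: 0 of 14 rose, 9 fell and 5 were not called (11 called when adjusted over the list alone, median -0.28, camera adjusted p = 7.46e-06). Muscle markers rose: 11 of 22 rose, 3 fell and 8 were not called (15 called when adjusted over the list alone, median 0.13, camera adjusted p = 0.000112). Of the pan-neuronal markers, 6 of 13 rose, 1 fell and 6 were not called (8 called when adjusted over the list alone, median 0.15, camera adjusted p = 0.000428). With the other combinations as reference, DptB, Drs, Hsp26 and Hsp68 were at -0.32, -0.62, -0.67 and -0.58, and sr, Ance and the activity-regulated list were no longer called (adjusted p = 0.432, 0.187 and 0.58). Fitted on these 2 groups alone, limma called 2294 probe sets in place of 4026.

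PTZ with oxaprozin, a nonsteroidal anti-inflammatory drug that inhibits cyclooxygenases, had lower DptB, Drs and Mtk than PTZ alone: they fell by 2.72 ± 0.061, 2.45 ± 0.048 and 2.11 ± 0.045 (DptB level 6.22 ± 0.099 against 8.94 ± 0.035, SD, n = 4 each, adjusted p = 1.77e-36). The activity-regulated transcription factor genes sr and Hr38 fell by 0.91 ± 0.083 and 0.81 ± 0.048, and Cyp4g1 by 2.38 ± 0.11. The mitochondrial genes ATPsynD and SdhB rose by 1.56 ± 0.061 and 1.18 ± 0.062, and Cpr72Ec, a cuticle protein gene, by 1.52 ± 0.059. Pxt, a cyclooxygenase-like peroxidase, lay near the lower end of the scale (2.42 ± 0.12 against 2.49 ± 0.10) and was not called (-0.073 ± 0.091, adjusted p = 0.601). For this combination limma called 3336 probe sets higher and 3350 lower (147 by at least 2-fold) and 10 of the 36 gene lists (4 also with an estimated correlation). Of the antimicrobial peptides and Toll/Imd effectors, 1 of 18 rose, 11 fell and 6 were not called (12 called when adjusted over the list alone, median -0.19, camera adjusted p = 0.000101). Activity-regulated genes fell: 0 of 14 rose, 9 fell and 5 were not called (9 called when adjusted over the list alone, median -0.31, camera adjusted p = 0.000347). Of the monoamine signalling genes, 2 of 26 rose, 13 fell and 11 were not called (17 called when adjusted over the list alone, median -0.18, camera adjusted p = 0.00078). Of the testis and accessory gland genes, 2 of 33 rose, 22 fell and 9 were not called (26 called when adjusted over the list alone, median -0.42, camera adjusted p = 2.84e-06). Set against the other combinations, DptB, Drs, Mtk, Cyp4g1, sr and Cpr72Ec were at -0.68, -0.73, -0.34, -0.75, -0.38 and 0.61, and the antimicrobial and activity-regulated lists were no longer called (adjusted p = 0.482 and 0.0849). The 5′ minus 3′ control signal was -4.73 ± 0.17 against -5.67 ± 0.089 in PTZ.

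The 5 drugs other than moxifloxacin, gemfibrozil and oxaprozin were fed both with and without PTZ, so the difference between their effects could be tested directly. It was called for 6693 probe sets with levetiracetam, 6842 with glucosamine, 8258 with mannitol, 8736 with olmesartan and 7942 with quinapril. DptB changed in opposite directions in the presence and absence of PTZ: with levetiracetam by 1.25 without PTZ and -2.11 with it (difference -3.36 ± 0.086, adjusted p = 1.14e-33), with glucosamine by 1.91 without PTZ and -2.93 with it (difference -4.84 ± 0.086, adjusted p = 8.97e-41) and with olmesartan by 2.87 without PTZ and -2.73 with it (difference -5.60 ± 0.086, adjusted p = 9.81e-44). Cyp4g1 changed with glucosamine by -5.63 without PTZ and 1.46 with it (difference 7.09 ± 0.16, adjusted p = 1.77e-36), and Acp98AB with mannitol by -7.30 without PTZ and 1.45 with it (difference 8.75 ± 0.17, adjusted p = 1.13e-39). CG13428 changed with olmesartan by 2.77 without PTZ and -3.05 with it (difference -5.83 ± 0.078, adjusted p = 3.51e-46) and TotC with quinapril by 2.80 without PTZ and -0.86 with it (difference -3.66 ± 0.11, adjusted p = 1.11e-31). Normal food and PTZ alone are the references of these contrasts, so their levels enter each of them: against the mean of the other groups of its kind DptB changed by -0.57 with levetiracetam without PTZ and by 0.055 with it. With the 5′ to 3′ signal as a covariate the quinapril difference was called for 4924 probe sets.

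Whether a second drug moved the transcriptome back toward normal food was asked by the slope of its change against PTZ on the PTZ change, across probe sets, which are not independent replicates; a slope of -1 would be a full return and 0 none. With the PTZ arrays split so that no array stood on both sides, the mean slope over 6 splits was 0.145 for levetiracetam, -0.134 for glucosamine, 0.0508 for mannitol, -0.0530 for olmesartan, -0.0169 for quinapril and 0.143 for oxaprozin. Without the split, unchanged groups gave a slope of -0.502 in simulation, and the measured slopes were 0.133, -0.150, 0.0370, -0.0683, -0.0316 and 0.131. The normal food arrays enter the PTZ change. Taken on the PTZ change of the other drug backgrounds, which shares no array with either group, the slopes were -0.343, -0.325, 0.296, 0.0249, 0.0735 and 0.259 in the same order, so that the sign for levetiracetam, olmesartan and quinapril turned.

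The other drugs were also compared with levetiracetam, the antiepileptic of the set, by correlating changes across probe sets, which again are not independent replicates. With the normal food arrays split, the correlation with levetiracetam was 0.755 for glucosamine, 0.626 for mannitol, 0.624 for gemfibrozil, 0.621 for olmesartan, 0.598 for quinapril and 0.377 for moxifloxacin. Unsplit values ran from 0.434 to 0.819, where unchanged groups gave 0.501 in simulation (0.411 for a group of 2 arrays), and unsplit covariances from 0.0531 to 0.117 against a simulated 0.00395. With disjoint sets of the other compounds as references in place of normal food, the correlation stayed above 0 for glucosamine (0.408), moxifloxacin (0.302) and gemfibrozil (0.0956) and turned for mannitol (-0.337), olmesartan (-0.367) and quinapril (-0.249). Among combinations against PTZ, the split correlation with PTZ and levetiracetam was 0.604 for oxaprozin, 0.213 for glucosamine, 0.190 for quinapril, -0.0255 for olmesartan and -0.233 for mannitol. The unsplit values were 0.672, 0.282, 0.265, 0.0195 and -0.200, with covariances of 0.0584, 0.0186, 0.0158, 0.00155 and -0.0168. With other combinations as references they were 0.551, 0.111, 0.0127, -0.322 and -0.348. Oxaprozin and levetiracetam were also the combinations with the higher 5′ minus 3′ control signals.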

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

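Of the tests in this part, these were chosen only after the result was seen: the gut list and the count of drug groups below normal food, the other combinations as reference, the level of PTZ beside the compounds without it, the combinations at the bioB level of PTZ, and the 5′ to 3′ slopes from disjoint groups and fits with that signal.

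Normal food had testis and accessory gland genes 2.96 higher (list median) than the mean of the 14 groups fed a compound, where 1 of its 33 genes lay above the median of all genes, against 23 in normal food; its most abundant genes there, Acp98AB, EbpII and Mst57Da, were at 10.22, 10.04 and 9.74 against 4.56, 3.42 and 4.71. Shorter transcripts do not account for it, since the list, groups fed a compound minus normal food, was at -3.03 with the 5′ to 3′ signal as a covariate and at -2.96 without it. Tissue from outside the head in the normal food RNA may account for the higher testis list: gut digestive enzymes (39 genes, 3 of them in another list and 3 above the median of all genes in the other heads) were 0.226 higher in normal food (camera adjusted p = 0.00121, Mal-A1 7.67 against 4.98). Against this, Mal-B2 and Mal-A5, that list's most abundant genes elsewhere, were lower in normal food (9.51 against 10.55 and 8.28 against 8.78). So were fat body genes (median -0.126, camera adjusted p = 0.0246), while muscle markers were not called (0.0706, 0.153). Pan-neuronal markers were higher there by 0.37 (camera adjusted p = 0.00136). Dup99B of the ejaculatory duct was at 2.43, against 2.32 in PTZ with oxaprozin and 7.13 in moxifloxacin. An effect of feeding on the transcripts stays open, because all 14 groups lay below the single normal food group and these readings cannot be told apart with one such group.

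PTZ with oxaprozin and PTZ with levetiracetam changed alike relative to PTZ (correlation across probe sets 0.604, genes not being independent replicates). The state of the PTZ arrays is not the whole source, since with disjoint other combinations as references the correlation was 0.551. With the 5′ to 3′ signal taken out of each change by slopes from disjoint sets of groups, the correlation was 0.396 (0.343 to 0.45 over splits) and the covariance 0.0622, against 0.0547 before, which argues against a linear dependence on the signal as the whole source. These slopes within groups correlated at 0.388 between the sets, and the signal differed from PTZ by 1.53 and 0.94, far beyond the highest SD within a group of 0.225. A part from RNA quality and an action shared by the compounds may both remain; the latter was not tested.

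Antimicrobial genes were lower in 5 of the 6 combinations than in PTZ. A high level in the PTZ arrays cannot be told apart from an effect of the combinations: relative to the 7 compounds without PTZ their list median was -0.00654, but 7 members were called higher and 6 lower, and Drs, Def, DptB and Mtk stood 2.08, 1.12, 1.04 and 0.65 above them. The bioB level alone does not account for it, as the 4 combinations at the level of PTZ were at -0.234, and with the 5′ to 3′ signal as a covariate the 5 combinations were at -0.279, against -0.208 without it. Bacterial load of the vials or day of feeding, which the labels do not give, and an effect of the combinations may each contribute.

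The bioB control stood at a mean of -1.34 relative to bioC on 20 arrays, against -4.99 to -4.22 on the other 38, in data that enter no comparison. Within the quinapril group it was -1.37 against -4.88 to -4.67 on replicate 4, and within olmesartan -1.44 against -4.57 to -4.43 on replicate 4. Counting those 2, single arrays stood apart from their group of 4 in 9 of 98 tests by Dixon's ratio, which chance alone does in about 1 of 20 groups. The testis and accessory gland median was 2.95 against 3.07 to 3.09 for olmesartan replicate 1 and 2.71 against 2.61 to 2.61 for PTZ with olmesartan replicate 4. The antimicrobial median was 6.42 against 6.62 to 6.63 for levetiracetam replicate 4. The P450 median was 6.75 against 6.65 to 6.66 for PTZ with mannitol replicate 3 and 6.82 against 6.68 to 6.70 for PTZ with oxaprozin replicate 1. The heat shock median was 9.34 against 9.41 to 9.42 for levetiracetam replicate 3, and the 5′ to 3′ signal -5.33 against -5.56 to -5.55 for mannitol replicate 2.

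Drug effects differed with and without PTZ by limma's test of the difference, in 6693 probe sets for levetiracetam, 6842 for glucosamine, 8258 for mannitol, 8736 for olmesartan and 7942 for quinapril; chance is not excluded for levetiracetam, as 6 of 100 regroupings gave as many. Ebp stood at 9.17 in normal food and 2.79 in PTZ, near the lower end of the scale, so a further fall with PTZ could hardly be measured. The levetiracetam differences included Ebp at 5.59, CG14645 at 4.78, DptB at -3.36 and Mtk at -2.94. For glucosamine they were 7.09 (Cyp4g1), 6.58 (Ebp), -4.84 (DptB) and -3.05 (Obp28a), and for mannitol 8.75 (Acp98AB), 7.63 (EbpII), -4.15 (Obp28a) and -3.44 (lectin-24Db). Olmesartan gave 5.28 for Ebp, 5.17 for CG31226, -5.83 for CG13428 and -5.60 for DptB, and quinapril 6.30 for Ebp, 5.42 for EbpII, -4.02 for DptB and -3.66 for TotC.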

How the results depend on the processing

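The fits with other references, the 5′ to 3′ signal, the bioB levels and pairs of group means were chosen after seeing the data. Under the variance trend, the second quantile normalization, the omission of dim probe sets, the replicate block and the fit on the groups compared, no named gene that was tested (251, or 244 without dim probe sets) lost its call or turned, and each of the 19 counts of calls stayed within 1.5 times its value, except PTZ with quinapril fitted on its 2 groups (2294 in place of 4026), where fewer arrays estimate the spread. Leaving out each array in turn ended none of the 251 named calls; without one moxifloxacin array the other is assumed to vary like the other groups. The second quantile normalization moved no share of higher calls by over 10 points and turned no called list. Of 229 called list tests, 124 held with an estimated correlation. Same-numbered arrays did not deviate together (correlations in the 14 comparisons from -0.16 to 0.11), so the numbers do not pair the arrays, and a replicate block gave 9433 calls for PTZ and 229 list calls. Low signal limits dim probe sets such as Pxt; signal over background is not given in these values.

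With the 5′ to 3′ signal as a covariate the calls were 4997 for glucosamine, 3419 for PTZ with levetiracetam and 4924 for the quinapril difference. With the bioB block (resting on 2 arrays) they were 2146 for PTZ with glucosamine and 3948 for PTZ with mannitol. PTZ over pairs of group means gave 554 calls in 6 pairs, 189 in 5 without normal food and 207 in 5 without glucosamine, where far fewer units are tested. In the same order, DptB was at -0.46, -1.10 and -0.14 and Mtk at -0.73, -1.13 and -0.59. Cyp4g1 was at 0.083 and 0.47 in the former 2 and Hsp68 at -0.046 and -0.33, while Acbp5 and Jon65Aiii turned in the 5 pairs without normal food (0.057 and 0.15). Of the 42 calls of genes named for PTZ, 13, 11 and 11 held in that order, and 25, 25 and 29 ended. Among all 251 named values, the calls of per, Clk, para and Trxr1 ended with the covariate (0.19, 0.12, 0.51 and 0.24), that of Sodh2 in PTZ with mannitol with the block, and none of 179 on the arrays of the lower bioB level. The cause was not tested for these or the following values.

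With the other groups of the same kind as reference, 200 of the named calls held, 12 ended and 19 turned: EbpII 0.12 and Cyp4g1 1.46 for PTZ; CG7953 0.28, Lsp2 -0.14, fit -0.47, DptB -0.57, Def -0.79, yip2 -0.43 and Jon65Aiii 0.44 for levetiracetam; Def -0.30 and Gfat1 -0.29 for glucosamine. The same held for CG18628 (1.70), CG7953 (0.99), Ebp (2.54) and CG8997 (0.60) with moxifloxacin, CG31226 (0.13) and CG18628 (1.03) with gemfibrozil, DptB (0.055) in PTZ with levetiracetam and Sodh2 (0.052) in PTZ with mannitol.

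Slopes on the PTZ change of the other backgrounds were -0.343, -0.325, 0.296, 0.0249, 0.0735 and 0.259 for levetiracetam, glucosamine, mannitol, olmesartan, quinapril and oxaprozin. Without splitting the PTZ arrays they were 0.133, -0.150, 0.0370, -0.0683, -0.0316 and 0.131 in that order. After the second quantile normalization the slopes of mannitol, olmesartan and quinapril were 0.0648, -0.0297 and 0.00256, and without dim probe sets those of levetiracetam, glucosamine, mannitol and oxaprozin were 0.164, -0.153, 0.0810 and 0.167. Leaving out arrays gave 0.130 to 0.161 for levetiracetam, -0.0661 to -0.0447 for olmesartan and -0.0313 to -0.0104 for quinapril.

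Correlations with levetiracetam for glucosamine, mannitol, olmesartan, moxifloxacin, gemfibrozil and quinapril were 0.819, 0.675, 0.671, 0.434, 0.681 and 0.648 unsplit and 0.408, -0.337, -0.367, 0.302, 0.0956 and -0.249 with other references. Without dim probe sets they were 0.763, 0.612, 0.608, 0.333, 0.598 and 0.583. With the 5′ to 3′ signal removed they were 0.752, 0.593, 0.385, 0.572 and 0.588 for these drugs without mannitol, and moxifloxacin was at 0.388 after the second normalization. Leaving out arrays gave 0.750 to 0.753 for glucosamine, 0.623 to 0.626 for mannitol and 0.362 to 0.370 for moxifloxacin. Between PTZ combinations, the correlations with the levetiracetam combination for glucosamine, mannitol, olmesartan, quinapril and oxaprozin were 0.282, -0.200, 0.0195, 0.265 and 0.672 unsplit and 0.111, -0.348, -0.322, 0.0127 and 0.551 with other references. With the 5′ to 3′ signal removed, the latter 4 were at -0.0957, 0.0192, 0.145 and 0.699, but the error of slopes shared by both changes enters these values, and with slopes of disjoint sets of groups oxaprozin was at 0.396. Without dim probe sets, mannitol, quinapril and oxaprozin were at -0.247, 0.232 and 0.647, and mannitol at -0.217 after the second normalization. Leaving out arrays gave -0.0468 to -0.00924 for olmesartan, 0.153 to 0.201 for quinapril and 0.588 to 0.605 for oxaprozin.

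Other splits of the same arrays were refitted. For the 13 comparisons of 4 with 4 arrays, only the real split of 35 gave as many calls. It gave 4026 to 9442, the highest other 65 to 5119. This excludes chance spread of arrays, not of cultures. Of 35 splits, 5, 5 and 14 matched the list counts of glucosamine, mannitol and olmesartan (real 18, 23, 21, highest other 19, 23, 23). For PTZ with levetiracetam, mannitol, olmesartan and oxaprozin 2, 8, 3 and 6 did (real 12, 13, 9, 10, highest other 13, 17, 10, 10). Matches count the real one. Mixed splits and regroupings keep drug or PTZ effects, so a match cannot decide on chance. In the other 6 comparisons the real split alone gave as many lists (real 19, 16, 18, 17, 19 and 18 for PTZ, levetiracetam, gemfibrozil, quinapril, PTZ with glucosamine and PTZ with quinapril, highest other 18, 13, 17, 16, 17 and 16). Of 100 drawn regroupings, 6 gave as many calls as the levetiracetam difference (6693, highest other 9087). For the differences of the 4 other drugs the real grouping alone did (7942 for quinapril, highest other 6002; 6842 and 6609 for glucosamine, 8258 and 6616 for mannitol, 8736 and 6544 for olmesartan). For PTZ over 6 pairs, 1 of 32 sign changes, the real one, gave 554 calls, with 0 as the highest other; limma was the tool.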

Other observations

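The fit over pairs of group means was chosen after seeing the data, and the list tested here was put together after Gnmt, CG3999, Nmdmc, Ahcy and Gart had been seen to rise with PTZ. The genes named here were chosen after their values were seen. The list holds 26 measured genes of folate, methionine, glycine and purine metabolism, 21 of them not looked at before. Over the 5 pairs of groups that share no array with normal food or PTZ alone, the unseen members had a median change with PTZ of 0.533. Camera gave p = 1.38e-07 for them, and p = 0.0647 with an estimated correlation. Of the unseen members 12 were higher in all 6 pairs, and 6 were called over the 5 pairs: Shmt, the serine hydroxymethyltransferase (1.33 ± 0.18), Sardh, sarcosine dehydrogenase (1.14 ± 0.11), Sam-S, which makes S-adenosylmethionine (0.61 ± 0.073), pug, a folate enzyme (0.75 ± 0.12), and Pfas and Paics of purine synthesis (1.23 ± 0.13 and 0.63 ± 0.093, limma). Others did not move with them: Ts, thymidylate synthase, was at -0.28 ± 0.076 and ras, IMP dehydrogenase, at -0.042 ± 0.11, neither called. A candidate explanation is that PTZ feeding raises one-carbon and early purine genes in each drug background; a shared handling of the PTZ vials could give the same values and was not tested.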
